A study of Mus musculus with 2 samples.

How the data were processed

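Lymphoid progenitors that carry the integrin α4β7 (αLPs) were profiled by droplet single-cell RNA sequencing in 1 library from mouse fetal liver and 1 library from adult mouse bone marrow. Per the labels' protocols, live cells of wild-type B6 mice were sorted by flow cytometry as lineage-negative, CD45-positive, CD127-positive, Flt3-negative, α4β7-positive and CD25-negative, with purity and viability both given as above 90%. CD127 is the interleukin 7 receptor encoded by Il7r, α4β7 is encoded by Itga4 and Itgb7, and CD25 is encoded by Il2ra. The antibodies of the lineage cocktail are not given in the sources used here. Per the series' design text, the fetal livers were taken at embryonic day 14.5. An age of 6 to 8 weeks stands in the labels of both samples, the fetal sample included, and was not used. Both samples carry the same batch label.

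The deposited files hold raw UMI counts per gene and cell barcode, that is, counts of distinct tagged RNA molecules, with no normalization. Per the labels' protocols, the libraries were made with a 10x Chromium 3' kit and sequenced on a NovaSeq 6000, UMIs were counted, and barcodes not associated with a cell were filtered out by the authors. Per the file headers, the matrices were written by software version 3.0.1 in matrix format version 2. The submitters' processing notes name the mouse build mm10 and Seurat 4.0 without saying what Seurat was used for. The aligner and the annotation release are not given in the sources used here. The deposited lists of gene identifiers and barcodes hold no measurements and are of no unit that was analysed (other). Of 27998 gene identifiers, 27645 were matched to GENCODE M21, an annotation of the same build, for coordinates, and no coordinates were printed for the rest.

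Before the data were examined, the cell filters, the gene lists, the cell type markers, the rule for named genes and most of the alternative settings were fixed. Barcodes with under 500 genes or over 10% of UMIs on mitochondrially encoded genes were left out. This removed 363 of 8946 fetal liver barcodes, 205 with too few genes and 301 with too many mitochondrial UMIs, and 109 of 7367 bone marrow barcodes, 87 and 62. Doublets, droplets that hold a pair of cells, were scored per library with Scrublet at an expected rate of 6%. It marked 2 fetal liver and 0 bone marrow cells, too few for the number of cells, so the caller did not work on these libraries and doublets remained in the data. After the data were seen, an alternative that left out the highest scores was added, which removed 554 fetal liver and 490 bone marrow cells. After all filters 8581 fetal liver cells with 91254234 UMIs and 7258 bone marrow cells with 29941097 UMIs were kept.

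Counts were summed over the kept cells of each library and divided by the library's total to give counts per 1000000 UMIs (CPM). A gene was compared by the log2 ratio of fetal liver over bone marrow CPM, with an exact conditional 95% interval from the split of its counts between the libraries. With 1 library per tissue there were no replicates, so no test between tissues was made and no p-value is given. All intervals, exact Clopper-Pearson intervals of shares included, and all limits for a count of 0, set at 3 counts, cover counting error only and say nothing of the spread between animals or preparations. A fold against 0 counts is given as a lower bound against 3 counts. The scaling assumes that the total RNA pool is comparable. A median-ratio size factor moved the median log2 ratio of all genes upward by 0.186 and a trimmed mean (TMM) factor, computed with edgeR 4.0.16, by 0.149.

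The named genes followed a rule of size. Over whole libraries these were the 10 largest and 10 smallest log2 ratios among genes with at least 50 CPM in the higher library, and, from each list, the 4 members with the largest absolute log2 ratio among those with at least 10 CPM. All gate genes and all innate lymphoid cell (ILC) lineage transcription factors with at least 50 CPM were named too. Within a class of cells the 5 largest and 5 smallest log2 ratios among genes with at least 100 CPM were taken. Gene models without a proper symbol, mitochondrially encoded genes and ribosomal protein genes were passed over. Genes named outside this rule were chosen after their values were seen. They are the lower-ranked members of some lists, the genes of the thinned shares and the genes described by cluster in the additional observations. Some genes that the rule took are not reported here.

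A total of 26 gene lists were fixed. They were gate genes, ILC lineage transcription factors, a B and T lymphoid programme, a fetal Lin28b programme, imprinted growth genes, S phase, G2 and M phase, MHC class I and class II presentation, interferon stimulated genes, migration and homing, egress, tissue residency, the Notch pathway, cytokine receptors, effector cytokines and cytotoxicity, glycolysis, oxidative phosphorylation, cholesterol synthesis, immediate early and stress genes, apoptosis and survival, haemoglobins, sex-linked genes, NF-kB and TNF signalling, ribosomal proteins and mitochondrially encoded genes. For members with at least 10 CPM in the higher library, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is no test of the tissues.

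Cells of both libraries were clustered together with scanpy 1.11.5 from 2000 variable genes, with 30 principal components, 15 neighbours and Leiden resolution 1.0. The variable genes were chosen with the library as batch key. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and the members of the S phase and G2 and M phase lists were kept out. Cell cycle genes outside these lists, such as Prc1 and Plk1, were not kept out, so cycling cells could still form clusters of their own. The libraries were not integrated, so a cluster mostly of 1 library may reflect that library and not a cell type. Clusters were named from 19 marker lists. A cluster took a list's name where at least 4 of its markers had at least 10 CPM and lay at least 2-fold above the other cells of the cluster's own library, where at least 1 marker stood among the 10 leading genes, and where no other list did as well on either count. The markers were fixed beforehand, but this rule was set after the clusters and their leading genes had been looked at. Names are written as "-like" and rest on the contrast within the cluster's own library.

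To compare shares of cells across depths, kept cells with at least 2000 UMIs were thinned at random to 2000, which left out 131 fetal liver and 1335 bone marrow cells. As background for shares of cells with a UMI, the share in the B lineage-like cluster of fetal liver (cluster 9) and in the lymphoid progenitor-like cluster of bone marrow (cluster 12) is given. These clusters were chosen after the data were seen. Cycling was read as at least 3 UMIs over the G2 and M phase list after thinning.

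The alternatives covered the cell filters, the kept doublets, 3 other scalings, weighting each cell or class the same, the CPM minimum, the clustering resolution, clustering each library alone or after thinning, other thinning depths and UMI minimums, and cells of a class with at most 1 G2 and M phase UMI. Weighting by class took only the classes with at least 50 cells in each library. These were the NK or ILC1-like and ILC2 progenitor-like cells, and all other cells were left out. Chosen after the data were seen were the removal of the highest doublet scores, the thinning of whole libraries, the removal of clusters 6 and 8 or of cluster 18, the comparison of clusters by number and the addition of bone marrow cluster 17 to the ILC2 progenitor-like cells. The computation was tested on simulated data. For whole libraries, 6386 genes were simulated with 200 changed, and the intervals held the true ratio for 95.1% of genes. Simulated folds of 2, 4, 0.5 and 0.25 came back at medians of 2.06, 4.08, 0.510 and 0.257. The counts were drawn from the Poisson model behind the intervals, so this coverage checks the computation only. In the real libraries UMIs can gather in few cells, which the intervals do not cover. Of the Il22 UMIs of bone marrow, 10 cells held 77.1%. Of simulated unchanged lists 6.5% fell outside the central 95% of random lists, and 100% of shifted lists lay above it. Most genes were unchanged in these simulated counts, so their ratios spread less than those of the real libraries. Cells simulated at a low and a high depth showed a median of 902 and 903 genes after thinning. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9 were used.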

Results

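αLPs, lymphoid progenitors marked by the integrin α4β7 from which innate lymphoid cells (ILCs) can arise, were compared between embryonic fetal liver and adult bone marrow. ILCs are lymphocytes without rearranged antigen receptors and comprise natural killer (NK) cells, ILC1, ILC2, ILC3 and lymphoid tissue inducer (LTi) cells. There was 1 library per tissue. The fetal liver library held 8946 barcodes with 91781395 UMIs and the bone marrow library 7367 barcodes with 30039931 UMIs. Kept cells had a median of 9290 UMIs and 2331 genes in fetal liver and of 3447.5 UMIs and 1249 genes in bone marrow, a 2.69-fold gap in UMIs per cell. The smallest level that 3 counts can show was 0.0329 CPM in fetal liver and 0.100 CPM in bone marrow.

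How the progenitors of the fetal and the adult organ differ was first read from the summed libraries. Fetal liver was higher in the cytokine genes Il22 and Lta, in the imprinted genes H19 and Dlk1 and in Cd3g, a component of the T cell receptor complex. Bone marrow was higher in Dntt, the terminal transferase of antigen receptor rearrangement, and in Areg, the growth factor amphiregulin. Of 6937 genes with at least 10 CPM in the higher library, 503 were at least 2-fold higher in fetal liver and 753 at least 2-fold higher in bone marrow, a count by size that comes from no test, and the median log2 ratio was 0.01.

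Il22 (mm10 chromosome 10, 118204942 to 118210047) stood at 126 CPM in fetal liver and 1.17 CPM in bone marrow, a log2 ratio of 6.75 with an interval of 6.27 to 7.27. Lta (chromosome 17, 35203165 to 35205351), which encodes lymphotoxin alpha, stood at 248 and 8.75 CPM, a log2 ratio of 4.82. H19 (chromosome 7, 142575529 to 142578143) stood at 98.7 and 1.24 CPM, and Dlk1 (chromosome 12, 109452823 to 109463336) at 67.5 and 0.735 CPM, log2 ratios of 6.32 and 6.52. Cd3g (chromosome 9, 44969572 to 44980431) reached 279 CPM against 7.01 CPM, a log2 ratio of 5.31 with an interval of 5.12 to 5.52. Cck (chromosome 9, 121489824 to 121495694), the gene of cholecystokinin, had 4566 UMIs, or 50.04 CPM, in fetal liver and 0 in bone marrow and was at least 499-fold higher. Of the other leading fetal liver genes, Mzb1 had a log2 ratio of 6.59, Ifitm1 of 5.35 and Apoe of 4.68. Ifitm1 rose to 7.26 without clusters 6 and 8, which held cells of other blood lineages.

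Dntt (chromosome 19, 41029275 to 41059525) was counted 1 time in fetal liver and 1919 times, at 64.1 CPM, in bone marrow, a log2 ratio of -12.51 with a counting interval of -17.82 to -10.03. Cpne2 and Bcas1 followed, with log2 ratios of -6.69 and -6.31, Bcas1 at 1.40 CPM in fetal liver and 111 CPM in bone marrow. Areg (chromosome 5, 91139599 to 91148432) stood at 11.0 and 160 CPM, a log2 ratio of -3.87, and at -3.10 among cells with at least 1000 genes. The chromatin remodeller Chd3 had a log2 ratio of -4.08, Ctla2a of -3.83, Clec2i of -3.81, the transcription factor gene Hlf of -3.67 and PISD, for which no coordinates were matched, of -3.33. The classes found in both libraries were the NK or ILC1-like and ILC2 progenitor-like cells. With only these cells, each class weighing the same, Il22 moved to 5.66, Lta to 3.36, H19 to 8.36 and Apoe to 6.35.

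The genes of the sorting gate were detected in both libraries, and those of the markers sorted for were lower in fetal liver over whole libraries. Il7r stood at 178 CPM in fetal liver and 417 CPM in bone marrow, a log2 ratio of -1.23, Ptprc, the gene of CD45, at -0.78, Itga4 at -0.61 and Itgb7 at -0.37. The median of the 4 measured gate genes was -0.69, at percentile 1.92 of random lists, with 1 member at least 2-fold higher in bone marrow and 0 in fetal liver. Flt3, sorted against, stood at 1.45 and 1.20 CPM, and Il2ra, sorted against as CD25, at 1.08 and 7.78 CPM.

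ILC lineage transcription factors were lower in fetal liver as a group over whole libraries, but not clearly in every comparison within a class or pair of clusters. Of 22 measured members 13 were at least 2-fold higher in bone marrow, 2 at least 2-fold higher in fetal liver and 7 lay within 2-fold, with a median log2 ratio of -1.12, below all 10000 random lists (percentile 0). Gata3, which directs ILC2 development, stood at 108 CPM in fetal liver and 420 CPM in bone marrow, a log2 ratio of -1.95 with an interval of -1.99 to -1.92. Sox4 had a log2 ratio of -1.96, Lmo4 of -1.58, Ets1 of -1.46, Rora of -1.45, Bcl11b of -1.38, Tox of -1.26, Tox2 of -1.16, Zbtb16 of -1.08 and Runx3 of -1.04. Zbtb16 encodes PLZF, a marker of the common ILC progenitor. Maf at -0.99, Id2 at -0.73, Ikzf2 at -0.55 and Tcf7 at -0.49 lay within 2-fold. At low levels in both libraries, Nfia reached -3.42, Lef1 -3.35 and Eomes, a transcription factor of NK cells, -2.80. Id3 stood at 1.92, and Runx1, within 2-fold, at 0.94.

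Programmes of fetal growth were higher in fetal liver. The fetal Lin28b programme had a median log2 ratio of 3.02, above all random lists (percentile 100), with 5 of 7 measured members at least 2-fold higher in fetal liver and 1 at least 2-fold higher in bone marrow. Igf2bp1, an RNA-binding protein of fetal cells, had 2049 UMIs in fetal liver and 0 in bone marrow and was at least 224-fold higher, Igf2bp2 had a log2 ratio of 4.65, Igf2bp3 of 3.88 and Arid3a of 3.02, whereas Mycn stood at -1.51. The imprinted growth genes had a median of 2.69 (percentile 100), with 4 of 5 measured members at least 2-fold higher in fetal liver, Igf2 at 2.69 and Cdkn1c at 2.15 among them. With each cell weighing the same the Lin28b median was 2.07, and with no CPM minimum and a pseudocount of 1 CPM the imprinted median was 0.76.

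B and T lymphoid genes did not move as a group. The median of 10 measured members was 1.49 (percentile 100), with 5 at least 2-fold higher in fetal liver and 2 in bone marrow, but it turned to -0.83 among members with at least 50 CPM. Cd79a, a component of the B cell receptor, had a log2 ratio of 6.59 and the surrogate light chain gene Igll1 of 6.45, while Dntt went the other way. With each class found in both libraries weighing the same, Cd79a stood at 1.57 and Igll1 at 0.18, so most of each difference lay outside these classes or in their proportions.

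Cell cycle genes were higher in fetal liver. Of 42 measured G2 and M phase genes 29 were at least 2-fold higher in fetal liver and 0 in bone marrow, with a median log2 ratio of 1.37 (percentile 100). Ube2c stood at 461 and 87.7 CPM, a log2 ratio of 2.39, and the mitotic kinase gene Cdk1 at 127 and 28.1 CPM, a log2 ratio of 2.17. Aurka had a log2 ratio of 2.17 and Hmmr of 2.09. Of 42 S phase genes 23 were at least 2-fold higher in fetal liver and 0 in bone marrow, with a median of 1.08 (percentile 100). Cdc45 had a log2 ratio of 1.66, Rrm2 of 1.60 and Cdc6 of 1.59.

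Glycolysis genes were higher in fetal liver too. Their median log2 ratio was 1.24 (percentile 100), with 9 of 16 measured members at least 2-fold higher in fetal liver. The lactate exporter gene Slc16a3 had a log2 ratio of 2.88, Tpi1 of 1.95 and Pkm of 1.75. The hexokinase gene Hk2 was the 1 member at least 2-fold higher in bone marrow, at 81.5 and 270.0 CPM, a log2 ratio of -1.73. Cholesterol synthesis genes had a median of 0.81 (percentile 99.97), with 2 of 11 measured members at least 2-fold higher in fetal liver, Mvd at 1.38 and Fdft1 at 1.05, and with Msmo1 at 0.89 and Fdps at 0.86. Oxidative phosphorylation genes had a median of 0.46 (percentile 98.8), and 41 of 42 lay within 2-fold. Atp5b stood at 0.85, Sdhd at 0.84 and Uqcrc1 at 0.84.

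**Figure D1:**
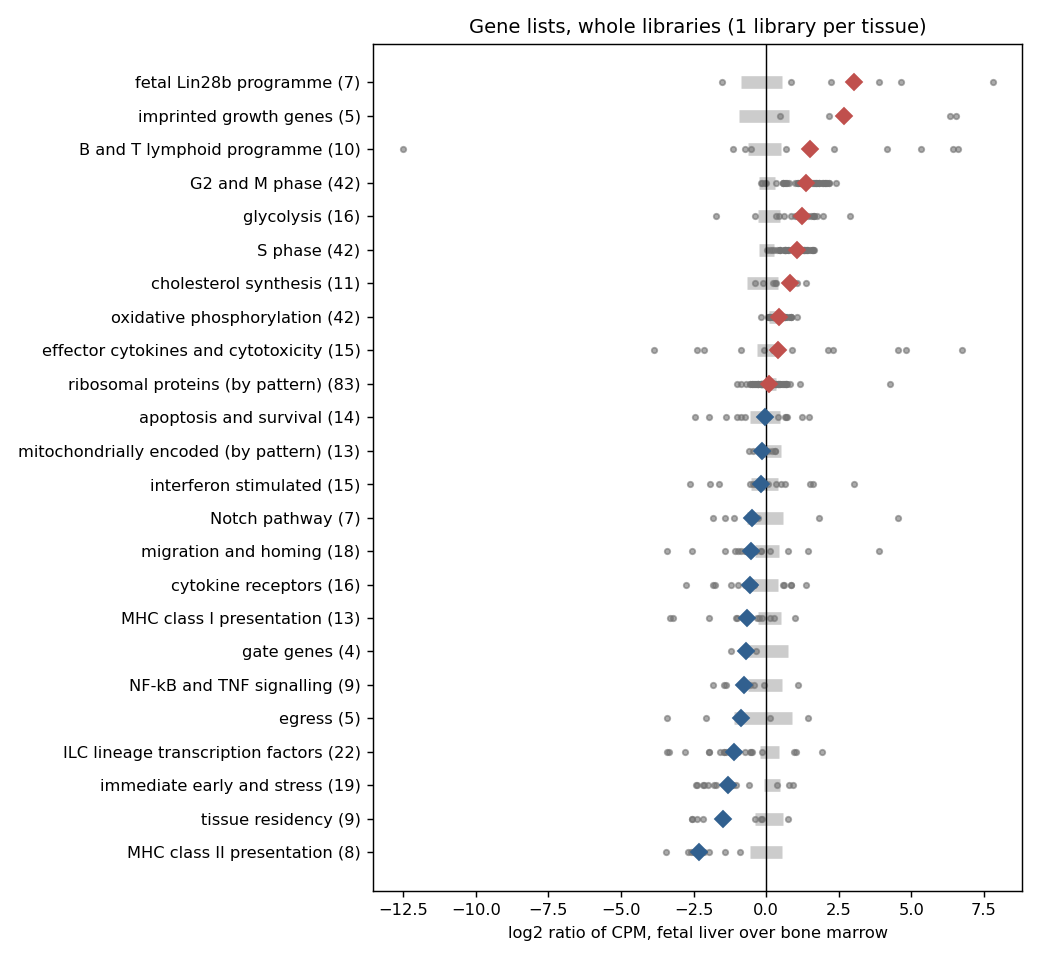
Median log2 ratio of fetal liver over bone marrow CPM for the gene lists, with the central 95% of 10000 random lists matched on mean expression; haemoglobins and sex-linked genes are left out. The fetal Lin28b programme lies highest at 3.02 and MHC class II presentation lowest at -2.32.

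Genes of antigen presentation were higher in bone marrow. MHC class II genes had a median log2 ratio of -2.32 (percentile 0), with 7 of 8 measured members at least 2-fold higher in bone marrow. The invariant chain gene Cd74 stood at 81.9 CPM in fetal liver and 359 CPM in bone marrow, a log2 ratio of -2.13, and H2-DMb1, H2-DMa, H2-Eb1 and H2-Aa had log2 ratios of -3.46, -2.70, -2.60 and -2.51. Bone marrow cluster 18, with 2.38% of cells, held 6677 of the Cd74 UMIs of bone marrow. Without it, an alternative chosen after the data were seen, the list median was -1.19, Cd74 stood at -0.76, H2-Aa at -1.25 and H2-Eb1 at -1.13, while H2-DMb1 stood at -3.31 and H2-DMa at -2.60. MHC class I genes had a median of -0.65 (percentile 0.075), with 5 of 13 at least 2-fold higher in bone marrow, B2m at -1.02 and H2-K1 at -1.05 among them, and 1, the immunoproteasome gene Psmb10 at 1.00, at least 2-fold higher in fetal liver. H2-Q4, H2-Q6 and H2-Q7 had log2 ratios of -1.97, -3.32 and -3.19. These genes are related in sequence, and H2-Q6 and H2-Q7 are near-identical. How the counting assigned reads among them was not examined, so their values are uncertain.

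Interferon stimulated genes split. Igtp and Gbp2 were at least 2-fold higher in fetal liver, with log2 ratios of 3.03 and 1.52, whereas Ifit1, Isg15 and Ifi203 were at least 2-fold higher in bone marrow, at -2.62, -1.95 and -1.63. The median of 15 measured members was -0.18 (percentile 26.5) and turned positive at 0.11 with a median-ratio size factor.

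Immediate early and stress genes were higher in bone marrow. Of 19 members 15 were at least 2-fold higher there and 0 in fetal liver, with a median log2 ratio of -1.32 (percentile 0). Fos stood at 651 and 2940 CPM, a log2 ratio of -2.18, and Zfp36, Fosb and Egr1 at -2.40, -2.40 and -2.14. NF-kB and TNF signalling genes had a median of -0.77 (percentile 0.94), and of -1.42 among members with at least 50 CPM. Of 9 measured members 3 were at least 2-fold higher in bone marrow, Tnfaip3 at -1.84, Nfkb1 at -1.45 and Nfkbid at -1.40, and 1, Icam1 at 1.11, in fetal liver.

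Tissue residency genes were higher in bone marrow by their median of -1.49 (percentile 0), with 5 of 9 measured members at least 2-fold higher there. Nr4a1 and Nr4a2, which are also immediate early genes, both stood at -2.57, Xcl1 at -2.40 and Rgs2 at -2.18. With no CPM minimum and a pseudocount of 1 CPM the median was -0.16. Migration and homing genes had a median of -0.52 (percentile 0.43), and 12 of 18 lay within 2-fold. The chemokine receptor gene Cxcr3 had a log2 ratio of 3.88 and S1pr1 of 1.44, whereas Cxcr4 stood at -2.54. Egress genes had a median of -0.87 (percentile 7.87) over 5 members, with Klf2 at -2.06 and Ccr7 at -0.87, and of -0.06 with no CPM minimum.

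Cytokine receptor genes had a median of -0.57 (percentile 1.61), with 4 of 16 measured members at least 2-fold higher in bone marrow and 1 in fetal liver. Il1rl1, the interleukin 33 receptor of ILC2, stood at 6.48 and 44.1 CPM, a log2 ratio of -2.77, Il17rb at -1.84, Il18r1 at -1.75 and Ifngr1 at 1.39. Effector genes had a median of 0.41 (percentile 94.7). Of 15 measured members 5 were at least 2-fold higher in fetal liver, among them Il22, Lta, Ifng at 4.54 and Il13 at 2.29, and 3 in bone marrow, Areg, Xcl1 and Ccl4 at -2.15. Notch pathway genes had a median of -0.50 (percentile 7.06), with the ligand genes Jag1 at 4.52 and Dll1 at 1.82 higher in fetal liver and Notch2 at -1.84, Hey1 at -1.42 and Hes1 at -1.12 higher in bone marrow. Apoptosis and survival genes had a median of -0.04 (percentile 45.8), with Bcl2 at -2.43, Bcl2a1b at -1.99 and Birc2 at -1.40. Among members with at least 50 CPM the median was -1.07.

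Haemoglobin genes had a median log2 ratio of 3.21 (percentile 100) over 4 members, Hba-a2 at 4.74, Hbb-bs at 3.94, Hbb-bt at 2.48 and Hba-a1 at 2.23. Hba-a1 turned to -0.40 without clusters 6 and 8, an alternative chosen after the data were seen. It turned to -0.89 with only the classes found in both libraries, each weighing the same. The list median rested on few cells. A single fetal liver cell held 49.1% of the 16624 haemoglobin UMIs and the 10 highest cells 87.4%, and without the 10 highest cells of each library 0 members reached 10 CPM. Of the sex-linked genes, Xist, the X-inactivation RNA, had 23013 UMIs, or 252 CPM, in fetal liver and 2 UMIs in bone marrow, a log2 ratio of 11.88 with a counting interval of 10.03 to 14.93. The Y-linked genes Ddx3y, Uty and Eif2s3y were detected in both libraries, at log2 ratios of -1.92, -1.92 and -1.24, so the list median of -1.58 (percentile 0.030) and mean of 1.70 differed in sign. Fetal liver thus held RNA of both sexes and bone marrow nearly only of males, and the sex of the animals was confounded with tissue in every comparison. Ribosomal protein genes had a median of 0.09 (percentile 0.24) and 80 of 83 lay within 2-fold. Rpl39l stood at 4.28 and Rps28 at -1.01. Mitochondrially encoded genes had a median of -0.13 (percentile 2.78), with all 13 within 2-fold, mt-Co1 at -0.60 the farthest from 0, and turned to 0.03 with a median-ratio size factor.

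Cells were then grouped to ask which ILC lineages each organ held. Both organs held NK or ILC1-like and ILC2 progenitor-like clusters. LTi or ILC3-like, B lineage-like and monocyte or macrophage-like clusters came from fetal liver, and ILC progenitor-like and lymphoid progenitor-like clusters from bone marrow. LTi or ILC3-like cells made up 18.6% of fetal liver cells (17.7 to 19.4) and 0.0138% of bone marrow cells. NK or ILC1-like cells made up 30.1% (29.2 to 31.1) and 6.78% (6.21 to 7.38), ILC2 progenitor-like cells 17.2% (16.37 to 17.98) and 47.5% (46.4 to 48.7). ILC progenitor-like cells, all in cluster 14, made up 27.1% of bone marrow cells and 0 of 8581 fetal liver cells. That 0 sets no limit on such cells in fetal liver, because the libraries were not integrated and clusters were named within each library. Fetal liver cluster 5, the best match of cluster 14, held 16.2% of fetal liver cells and stayed unnamed. Lymphoid progenitor-like cells made up 13.3% of bone marrow and 0.0117% of fetal liver, B lineage-like cells 2.11% of fetal liver and 0.0138% of bone marrow, and monocyte or macrophage-like cells 0.117% of fetal liver and 0 of 7258 bone marrow cells. Interferon response genes such as Iigp1 and Gbp2 were among the leading genes of fetal liver clusters 1 and 11, which are ILC2 progenitor-like and NK or ILC1-like.

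These shares depended on the grouping of cells. Of 19 clusters 13 were named, 18 held over 99% of their cells from 1 library and the remaining cluster 6 held 90.2%. Unnamed clusters held 31.9% of fetal liver and 5.26% of bone marrow cells. The naming rule kept bone marrow cluster 18 (2.38%), in which 10 LTi or ILC3 markers were raised, out of the LTi or ILC3-like class because MHC class II genes led it. It kept fetal liver cluster 5 (16.2%), with 5 raised ILC progenitor markers, and cluster 7 (8.76%), with 6 raised lymphoid progenitor markers, out of the classes found in bone marrow. Fetal liver minus bone marrow, the NK or ILC1-like difference of 23.4 percentage points turned to -25.3 at Leiden resolution 0.5 and to -6.89 with cells thinned before clustering, so no order is read from it. The ILC2 progenitor-like difference of -30.4 shrank to -1.09 with each library clustered alone, the ILC progenitor-like name was given to no cluster in 4 of the 7 alternatives, and the LTi or ILC3-like difference of 18.6 stayed between 14.2 and 19.6. In each alternative the rule again left a bone marrow cluster with raised LTi or ILC3 markers unnamed, so this range rests partly on the rule. At resolution 2.0 it also left unnamed a cluster of 670 fetal liver cells with 11 such markers raised. The sort against Flt3 and CD25 and the 2.69-fold depth gap can both set such shares.

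**Figure D2:**
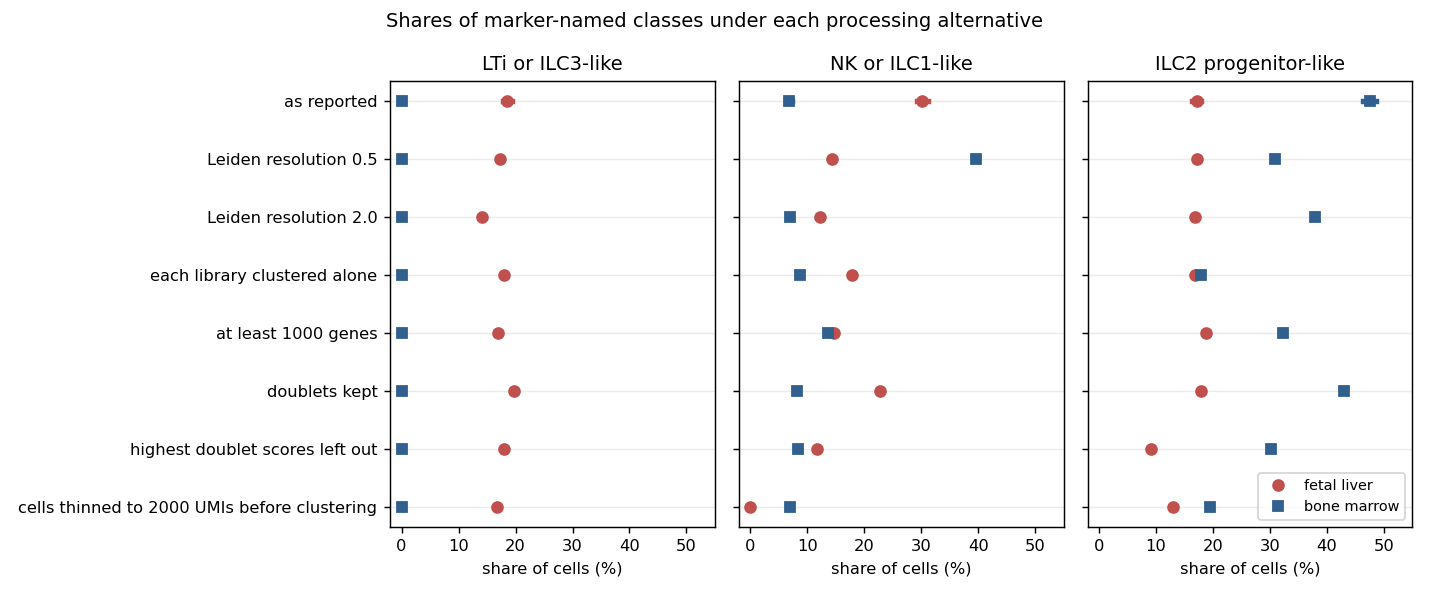
Percentage of kept cells per class in fetal liver and bone marrow as reported, with 95% exact intervals, and under the other ways of clustering. The LTi or ILC3-like share is higher in fetal liver throughout, while the NK or ILC1-like order turns.

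At equal depth, the ILC2 genes Gata3, Il1rl1 and Areg were detected in more bone marrow cells, whereas the ILC2 cytokine gene Il13 and the LTi or ILC3 genes Lta and Il22 were detected in more fetal liver cells. Thinning kept 1172 of the 2281 bone marrow cells of ILC2 progenitor-like cluster 16. The bone marrow shares thus leave out many shallow cells of that cluster. After thinning to 2000 UMIs, Gata3 was detected in 17.9% of fetal liver cells (17.1 to 18.8) and 52.5% of bone marrow cells (51.2 to 53.7), and in 48.6% and 69.2% before thinning. Il1rl1 was detected in 1.18% and 6.53%, Areg in 2.00% and 11.0% and Zbtb16 in 5.41% and 12.5%. Il13 was detected in 2.69% (2.35 to 3.05) and 0.743% (0.540 to 0.996) and Il4 in 3.86% and 3.85%. Lta was detected in 19.2% and 1.91% and Il22 in 8.82% (8.22 to 9.44) and 0.236% (0.129 to 0.396). Of the NK or ILC1 factors, Tbx21 was detected in 1.49% and 0.321% and Eomes in 0.521% and 2.72%. In the background clusters, with median depths of 9417 UMIs in fetal liver and 6704 UMIs in bone marrow, Gata3 was detected in 0.562% and 22.2%, Il1rl1 in 0.562% and 0.742%, Areg in 1.69% and 2.65%, Zbtb16 in 0.562% and 5.51%, Il13 in 0% and 0%, Il4 in 0.562% and 0.424%, Lta in 2.81% and 0.212%, Il22 in 0% and 0%, Tbx21 in 0% and 0.212% and Eomes in 0% and 0.318%. Before thinning, the fetal liver and bone marrow shares were 4.74% and 13.6% for Il1rl1, 5.79% and 17.98% for Areg, 22.6% and 18.9% for Zbtb16, 8.94% and 1.28% for Il13, 14.45% and 7.08% for Il4, 33.6% and 3.28% for Lta, 14.52% and 0.248% for Il22, 6.61% and 0.524% for Tbx21 and 2.26% and 3.93% for Eomes. Flt3 lay at 0.189% and 0.186%, against 1.12% and 0.424% in the background clusters. Flt3 is itself on the lymphoid progenitor marker list, so these clusters cannot serve as background for it.

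**Figure D3:**
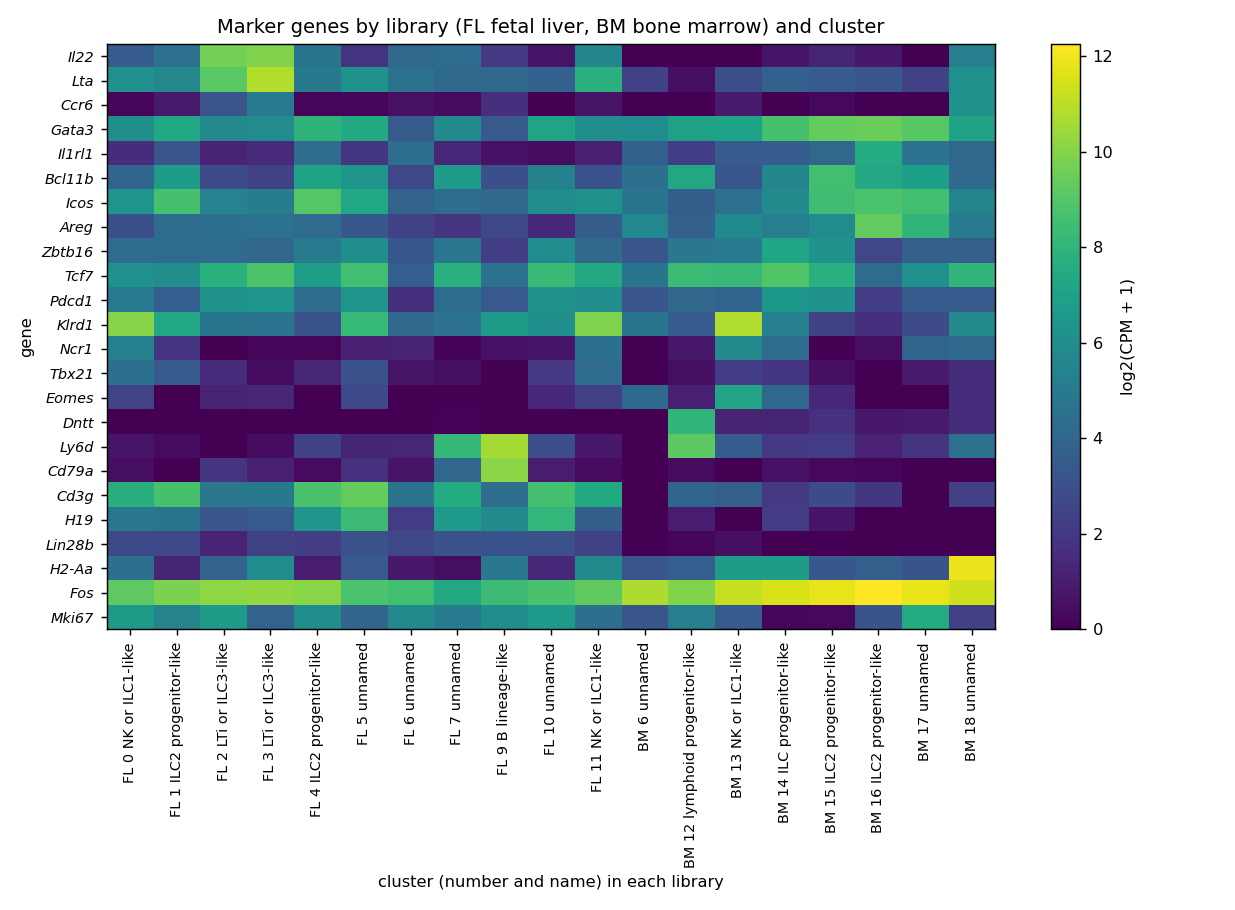
Log2 of CPM plus 1 of marker genes by library and cluster. Groups of few cells, such as cluster 8 with 10 cells, are left out. Il22 and Lta reach 995 and 1852 CPM in fetal liver cluster 3, and Areg reaches 642 CPM in bone marrow cluster 16.

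More fetal liver than bone marrow cells carried G2 and M phase RNA at equal depth. At least 3 UMIs of the list were found in 81.6% of thinned fetal liver cells (80.8 to 82.5) and 46.8% of bone marrow cells (45.5 to 48.1), and in 97.8% and 67.1% before thinning. The order was that of the list's CPM. The difference of 34.8 percentage points fell to 10.6 at 4000 UMIs and rose to 42.0 with at least 5 UMIs. The share marks a range and not a type, since 18.8% of fetal liver and 36.4% of bone marrow cells held 2 or 3 such UMIs, next to the threshold. Among ILC2 progenitor-like cells it was 91.5% in fetal liver and 43.4% in bone marrow, and among NK or ILC1-like cells 87.2% and 40.1%. Only 2301 of the 3450 bone marrow ILC2 progenitor-like cells had 2000 UMIs. Thinned to 1000 UMIs, where 3437 of them remained, the ILC2 progenitor-like shares were 75.1% in fetal liver and 15.9% in bone marrow. Within fetal liver the share at 2000 UMIs was 62.3% and 100% in LTi or ILC3-like clusters 3 and 2 and 99.9% and 78.1% in NK or ILC1-like clusters 0 and 11. Within bone marrow it was 75.7% in the lymphoid progenitor-like cluster, 35.0% in the ILC progenitor-like cluster and 100% in unnamed cluster 17, whose 156 cells were led by cell cycle genes. The bone marrow classes leave these cells out, and with cluster 17 added, an alternative chosen after the data were seen, the share among ILC2 progenitor-like cells of bone marrow was 47.0% and their mean 4.55 UMIs of the list in place of 3.03. Free RNA of dividing cells was not measured separately in the libraries and remains open for these shares.

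**Figure D4:**
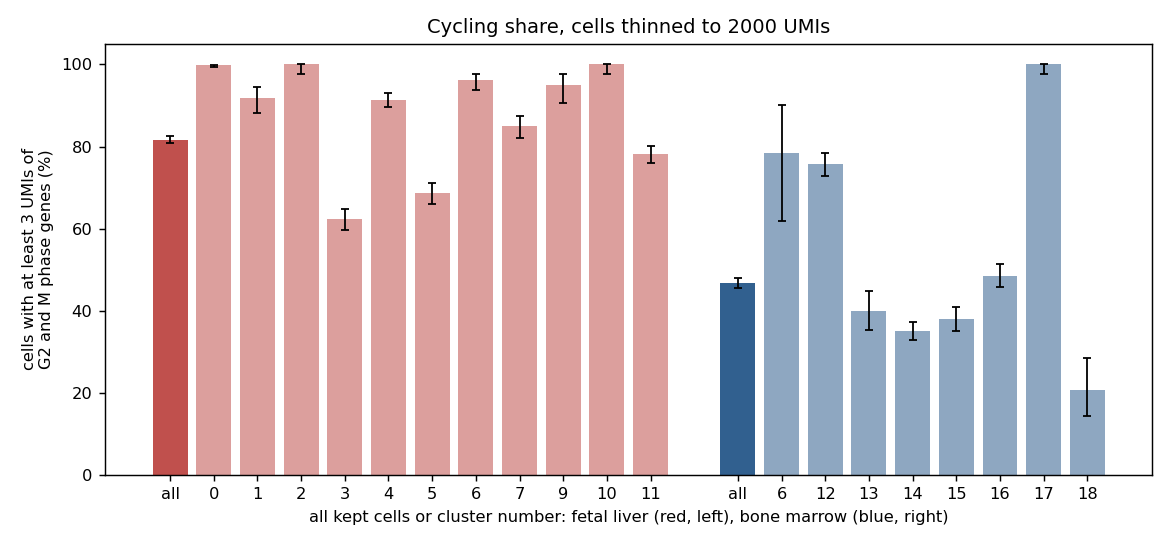
Percentage of cells thinned to 2000 UMIs that hold at least 3 UMIs of G2 and M phase genes, for all kept cells and for each cluster, with 95% exact intervals. Over all cells it is 81.6% in fetal liver and 46.8% in bone marrow.

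Within ILC2 progenitor-like cells, which were clusters 1 and 4 in fetal liver and 15 and 16 in bone marrow, the fetal cells were higher in cell cycle and fetal growth genes and the bone marrow cells in MHC genes and Areg. Slc38a4 was counted 1 time in bone marrow and stood at 101 CPM in fetal liver, a log2 ratio of 10.07 with a counting interval of 7.59 to 15.38. Ifitm1 had a log2 ratio of 8.13, the granzyme gene Gzma of 6.78 and Cd3g of 6.37, with Cd3g at 418 and 5.05 CPM. Xist again led. Bcas1 had a log2 ratio of -7.34, Ctla2a of -4.84 and Areg of -4.29 with 18.8 and 367 CPM, and the near-identical H2-Q6 and H2-Q7 of -7.50 and -6.55. The G2 and M phase median was 3.16, with 40 of 44 measured members at least 2-fold higher in fetal liver, S phase 1.92, the Lin28b programme 2.19 and glycolysis 1.59. The cell cycle medians depended on unnamed bone marrow cluster 17, which was led by cell cycle genes. With its 156 cells added, an alternative chosen after the data were seen, the G2 and M phase median was 1.55 and S phase 1.56. MHC class I stood at -1.53, MHC class II at -3.13, NF-kB and TNF signalling at -1.80, immediate early and stress genes at -1.62 and ILC lineage transcription factors at -1.34. The cells had a median of 11334 UMIs in fetal liver and 2565 in bone marrow. Among the 60 fetal liver and 801 bone marrow cells with at most 1 G2 and M phase UMI, the MHC class II median was -1.44. In the matching of clusters described below, bone marrow cluster 15, with 1163 cells, correlated more with unnamed fetal liver cluster 5 (0.459). Its values with clusters 4 and 1 were 0.315 and 0.167. It was thus not established that both sides of this class hold the same cell type.

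Within NK or ILC1-like cells, clusters 0 and 11 in fetal liver and mostly 13 in bone marrow, the fetal cells were higher in cell cycle genes and the bone marrow cells in Eomes and Ccl4. Apoe was counted 3 times in bone marrow, a log2 ratio of 7.55 with a counting interval of 6.00 to 9.83. Ifitm1 had a log2 ratio of 5.63, the creatine kinase gene Ckb of 4.88 and the cyclin gene Ccnb2 of 4.52, and Xist led with 6402 UMIs against 0. Prss2 had a log2 ratio of -7.11, Alox5ap of -5.33, Eomes of -4.92 with 4.57 and 139 CPM, Igfbp4 of -4.35 and the chemokine gene Ccl4 of -4.27. The G2 and M phase median was 2.34, with 35 of 44 measured members at least 2-fold higher in fetal liver, and the Lin28b programme stood at 2.89. Unnamed bone marrow cluster 17, led by cell cycle genes, was left out of this class. The median with its cells added was not computed here, so the size of the cell cycle difference may depend on where cycling cells were grouped. Effector genes split, with a median of 1.47, 9 of 16 measured members at least 2-fold higher in fetal liver and 4 in bone marrow, and with 0.296% of all UMIs in fetal liver and 0.381% in bone marrow. ILC lineage transcription factors had a median of -0.14 (percentile 4.16), with 5 of 22 measured members at least 2-fold higher in fetal liver and 7 in bone marrow. Immediate early and stress genes stood at -1.24 and MHC class II at -1.29, whereas MHC class I stood at 0.55. The class was not stable across clusterings. In the matching of clusters described below, fetal liver cluster 0 correlated about equally with bone marrow clusters 17 (0.259) and 13 (0.257). Fetal liver cluster 11 correlated most with cluster 18 (0.420) and less with cluster 13 (0.144). Seen from bone marrow, cluster 0 was the best match of cluster 13. Whether both sides hold the same cell type was thus not established.

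After the data were seen, clusters were also matched across libraries over 3398 genes, which are not independent replicates. The log2 CPM of each gene was first centred on its mean over the clusters of the same library. Pearson correlations were taken of these deviations, so they do not measure how alike the whole profiles are. Fetal liver cluster 5 and bone marrow cluster 14 matched best in both directions (0.586), as did 7 and 12 (0.634), 3 and 18 (0.575), 4 and 17 (0.449) and 1 and 16 (0.417). ILC2 progenitor-like cluster 4 of fetal liver thus matched the unnamed cycling cluster 17 best, followed by cluster 16 (0.395). Xist was among the 5 leading fetal liver genes in every pair. As log2 ratios, cluster 5 was higher than 14 in Ifitm1 (9.67), Cd3g (7.74) and H19 (6.63) and in Cck, with 3845 UMIs against 0. It was lower in H2-Q6 (-6.69), H2-Q7 (-6.35), Bcas1 (-5.27) and Clec2i (-3.75). Cluster 7 was led over 12 by the granulocyte genes S100a8 and S100a9, but 2 cells held 99.5% of the S100a8 UMIs. Without these cells Mzb1 stood at 6.81, Apoe at 5.13, Ifitm1 at 4.58 and Cd3g at 3.69, and H2-Q7 at -6.89, Cpne2 at -6.39, Serpine2 at -4.38 and Egr1 at -4.06. Dntt had 1 UMI in cluster 7 and 1881 UMIs in cluster 12. Cluster 3 was higher than 18 in Lta (4.73) and Il22 (4.71), in Dlk1, with 1315 UMIs against 0, and in Spns1, with 1 bone marrow UMI and a log2 ratio of 6.35 (counting interval 3.87 to 11.66). It was lower in Ms4a4c, with 0 UMIs against 57, in the MHC class II genes H2-DMb1 (-7.95), H2-DMb2 (-7.19) and H2-Eb1 (-6.39) and in Ccl4 (-7.69). Cluster 4 was higher than 17 in Cd3g, with 5806 UMIs against 0, and lower in Ctla2a (-4.20) and Areg (-3.79), and cluster 1 was higher than 16 in Ifitm1 (9.74) and Ifng (9.24) and lower in H2-Q6 (-6.41), Ctla2a (-5.63) and Areg (-5.08). In the order of 5 and 14, 7 and 12, 3 and 18, 4 and 17 and 1 and 16, G2 and M phase genes had medians of 2.05, 0.45, 1.47, -0.82 and 2.49, so the cell cycle difference was not found in every pair, and the Lin28b programme of 3.01, 3.82, 1.99, 2.51 and 3.53. ILC lineage transcription factors stood at -1.16, -0.48, -0.11, -0.22 and -0.58, with 3 and 18 and 4 and 17 within the central 95% of random lists, MHC class II at -3.06, -1.92, -5.80, -2.44 and -2.45, and glycolysis at 1.13, 1.16, 0.85, 1.38 and 1.78.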

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

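The removal of the highest doublet scores, the thinning of whole libraries, the removal of clusters 6 and 8 or of cluster 18, the addition of cluster 17 and the comparison of clusters by number were chosen after the data were seen, and the other alternatives were fixed before. A value counted as moved where it left its counting interval or, for a list median, the interval from resampling the list's members. No cause was tested for any value in this paragraph. Of 1590 alternatives for 133 genes taken by the naming rule or named, 1587 kept the sign of the log2 ratio and 535 moved, 339 of these toward 0. With only the NK or ILC1-like and ILC2 progenitor-like classes, each weighing the same, the sign turned for Flt3 (-3.68) and Hba-a1 (-0.89). Without clusters 6 and 8 the sign turned for Hba-a1 (-0.40). Of 255 alternatives for 26 list medians 245 kept their sign, and of 275 for 50 medians within classes 261 did, while 95 of 99 for 33 thinned shares kept theirs and 80 moved. No paired analysis was possible because there was 1 library per tissue. For the B and T lymphoid programme the median turned to -0.83 at a minimum of 50 CPM, where it was -1.07 for apoptosis and survival genes, and the haemoglobin median was 2.10 with no minimum. With each cell weighing the same the G2 and M phase and S phase medians were 1.87 and 1.43, and S phase was 1.28 with thinned cells. Without cluster 18 the MHC class II median was -1.19. A median-ratio size factor gave 0.62 for oxidative phosphorylation, 0.97 for cholesterol synthesis and 0.26 for ribosomal proteins. Within ILC2 progenitor-like cells it gave S phase 2.22, cholesterol synthesis 1.34, oxidative phosphorylation 0.96, ribosomal proteins 0.44, mitochondrially encoded genes 0.060, MHC class II -1.76 and immediate early genes -1.27, and thinning gave immediate early genes -1.41. Adding bone marrow cluster 17 to that class gave G2 and M phase 1.55 and S phase 1.56. Cells of that class with at most 1 G2 and M phase UMI gave G2 and M phase 0.98, a value lowered by the selection itself, oxidative phosphorylation 0.41, gate genes -0.58, migration -0.24, MHC class II -1.44 and immediate early genes -1.07. Within NK or ILC1-like cells such cells gave G2 and M phase 0.52, lowered in the same way, S phase 1.64, oxidative phosphorylation 0.53 and cytokine receptors 0.38. Thinning gave 2.78, 1.43 and 0.49 for the first 3 of these lists, and the median-ratio factor gave oxidative phosphorylation 0.51, ribosomal proteins 0.059 and MHC class II -1.16. Class shares, as fetal liver minus bone marrow percentage points, moved in 28 of 35 alternatives and turned sign in 2. In the order of resolution 0.5, resolution 2.0, each library alone, at least 1000 genes, doublets kept, highest doublet scores left out and thinning before clustering, NK or ILC1-like cells gave -25.3, 5.22, 9.16, 1.11, 14.7, 3.28 and -6.89. ILC2 progenitor-like cells gave -13.7, -21.0, -1.09, -13.4, -25.0, -21.0 and -6.45. ILC progenitor-like cells gave 0 in the first 4, where no cluster took the name, then -30.2, -12.4 and -34.1. LTi or ILC3-like cells moved to 17.3 at resolution 0.5, 14.2 at 2.0, 16.95 with at least 1000 genes, 19.6 with doublets kept and 16.7 with thinning. Lymphoid progenitor-like cells moved to 0 at resolution 2.0 and with each library alone, -18.0 with at least 1000 genes and -15.7 with thinning. Keeping doublets added only 2 cells, so the values under it also show how far the clustering alone can move. The cycling difference was 22.6 with at least 2 UMIs, 42.0 with at least 5, 39.9 at 1000 UMIs and 10.6 at 4000 UMIs. At 4000 UMIs the differences in thinned shares turned for Id2 (3.67) and Itgb7 (2.43). Thinning to 2000 UMIs left out 1335 bone marrow and 131 fetal liver cells.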

Other observations

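The tests of the 3 patterns weighed here, on S100a8, on the separation of the libraries and on immediate early genes, were chosen after the results were seen, and the genes described by cluster were picked after their values were seen.

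Ifng and the genes Igtp, Gbp2 and H2-K1 were highest in the same fetal liver clusters, while the fixed list of interferon stimulated genes had a median log2 ratio of -0.18 between the libraries and members on both sides. Ifng stood at 443 CPM in NK or ILC1-like cluster 0, 434 CPM in NK or ILC1-like cluster 11 and 428 CPM in ILC2 progenitor-like cluster 1, and at most at 66.0 CPM, in cluster 5, in the other fetal liver clusters. In the same 3 clusters Igtp, an interferon gamma induced GTPase, stood at 177, 255 and 246 CPM, against at most 42.6 CPM in cluster 2 and lower values in the other fetal liver clusters, and Gbp2 at 46.8, 86.8 and 107 CPM, against at most 5.07 CPM elsewhere in that library. H2-K1 stood at 630, 986 and 404 CPM there, against 284 CPM in cluster 2, 236 CPM in cluster 3 and 50.4 to 113 CPM in the remaining fetal liver clusters, while the bone marrow clusters lay between 437 and 958 CPM. The MHC class I difference between the tissues was therefore not uniform across fetal liver clusters. In bone marrow, Isg15 and Ifit1 stood at 96.0 and 57.4 CPM in cluster 13 and at 202 and 52.0 CPM in cluster 18, with Ifng at 32.0 and 2.00 CPM.

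Other gene pairs parted within a library. Fetal liver held 279 CPM of Cd3g but 26.2 CPM of Cd3d and 3.67 CPM of Cd3e, the other CD3 genes, and Cd3g was highest at 652 CPM in unnamed cluster 5. Bone marrow cluster 18, in which LTi or ILC3 markers were raised, held 13350 CPM of Cd74 and 3769 CPM of H2-Aa, against at most 376 and 106 CPM in the other bone marrow clusters, whereas fetal liver cluster 3, its best match, held 265 and 61.5 CPM. Of the ILC2 cytokines, Areg stood at 642 CPM in bone marrow cluster 16 and Il13 at 16.1 CPM, and fetal liver clusters 1 and 4 showed the opposite order, with Il13 at 66.1 and 49.6 CPM and Areg at 18.9 and 18.8 CPM. Xist and the Y-linked Ddx3y were both present in every fetal liver cluster described, at 164 to 418 CPM and 9.56 to 25.2 CPM.

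S100a8 and S100a9, granulocyte genes, led fetal liver cluster 7. Free RNA is argued against, since cells with at least 10 UMIs held 99.5% of the S100a8 UMIs of the cluster, and so is expression by the cluster as a whole, since 1.86% of its cells held any. The 10 highest cells held 99.9%, so a candidate source is a few cells or doublets of the granulocyte lineage. Of the 752 cells, 2 held at least 10 such UMIs, both also had S100a9 and Camp, and neither had Ly6d, Cd3g or Mpo. The cells were sorted as lineage-negative, but the antibodies of the lineage cocktail are not given in the sources used here, so whether the sort should have removed granulocytes is not known. No biological explanation was tested.

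Nearly every cluster came from 1 library. The depth gap between the libraries is argued against as the whole cause, since after every cell was thinned to 2000 UMIs 98.98% of cells still lay in clusters with at least 90% of their cells from 1 library. Tissue and age against handling of the library cannot be told apart with 1 library per tissue, so a biological difference remains open and untested. The sex of the animals differed between the libraries as well, with 23013 Xist UMIs in fetal liver and 2 in bone marrow. As the whole cause sex is argued against, since the fetal liver clusters described also held Y-linked RNA. Bone marrow clusters 12 and 13 held 1 fetal liver cell each and clusters 14 to 18 held 0, so male fetal cells did not join them. Sex-linked genes were also kept out of the clustering. A part played by sex remains open.

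Immediate early and stress genes were higher in bone marrow. A difference in the shares of the named classes and matched clusters is argued against as the whole cause. The list median lay below -0.5 in 7 of the 7 comparisons within a class or pair of clusters, some of which share cells. It was not established that both sides of a comparison hold the same cell type. Differences of cell type inside the comparisons therefore remain open. The depth gap between the libraries remains open. Among cells of either library with 4000 to 8000 UMIs the median was -0.86, closer to 0 than the -1.32 of all cells but not near it, and these cells had a median of 6092 UMIs in fetal liver and 5235 in bone marrow. A choice by depth also changes which cell types are compared, so the shift cannot be read as depth alone. Of 2887 bone marrow cells with at least 4000 UMIs, 818 were in cluster 12 and 225 in cluster 16. Among all 7258 bone marrow cells these clusters held 963 and 2281. Tissue and age against handling during the sort cannot be told apart with 1 library per tissue, because these genes respond to stress during cell isolation as well as to signals in the tissue.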
